A study of Ovis aries with 6 samples.

How the data were processed

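PolyA RNA of the choroid plexus of ewes was sequenced in 6 pools, 2 each from ewes in short days, ewes in long days and thyroidectomised ewes in long days. The series' design text gives 8 ewes per group, 7 in the THX group, and 3 to 4 ewes per pool, with equal amounts of RNA from each ewe. Libraries were made with a stranded mRNA kit per the labels. Per the submitters' processing notes, bcl2fastq 2.20, FastQC 0.11.8, MultiQC 1.9, TopHat2 2.1.1, SAMtools 1.9 and featureCounts 2.0.0 were used. The deposited values are raw counts per gene, whole numbers that the authors did not normalise. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so counts of overlapping or antisense genes carry that uncertainty. No positions on the genome were used.

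Identifiers were matched to a table of the sheep reference annotation for names alone. Of the 33609 identifiers listed, 28100 were in that table, and of the 15527 listed without a symbol 471 were given a name by it. Among the 18019 tested genes, 3747 had no symbol and 92 shared a symbol with another identifier. Total counts per pool ran from 48282883 to 82100653. Within groups the counts of the 2 pools differed by 28.3 (Short), 15.8 (Long) and 70.1 (THX) times the variance expected of counting alone, so the pools were not repeat sequencing of 1 library.

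All fits were made in R 4.3.3. Genes with low counts were removed by the default expression filter of edgeR 4.0.16 for the 3 groups, counts were scaled by TMM factors, and a quasi-likelihood model with 1 mean per group was fitted to all 6 pools, which leaves 3 residual degrees of freedom, with 3.96 prior degrees of freedom added by moderation. The common biological coefficient of variation was 0.151. Each pair of groups was compared by a two-sided quasi-likelihood F test, adjusted over all tested genes by the Benjamini-Hochberg method, and genes with an adjusted p under the threshold of 0.05 are said to have risen, fallen or changed. CPM values use TMM-scaled totals, except those of the pituitary genes in the last paragraph, which use total counts. The log2 differences and their SE come from the same model. Alternatives used DESeq2 1.42.0 and the voom method of limma 3.58.1.

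Gene lists were tested by camera of limma with the inter-gene correlation preset at 0.01, which compares a list with all other genes, and by camera with an estimated correlation and by fry, which tests the list alone for a shift in 1 direction. Of 41 lists, 39 had at least 5 tested members and were adjusted together within each comparison. The lists of red blood cell markers and of mitochondrially encoded genes had fewer and were not analysed here. Counts adjusted over the list alone apply the Benjamini-Hochberg method to the members of 1 list. The members, groups, comparisons, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, for each comparison, the 10 largest increases and the 10 largest decreases among called genes with a symbol, a mean CPM of at least 2 and no overlap between the groups, and the 5 most abundant called genes. It added up to 4 members with the lowest p of each list described, and KLF9, HR, DIO1, DIO3, THRB and TTR in every comparison. Some of the genes that the rule takes are not reported here.

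The shared change of thyroidectomy and short days was measured by the correlation and covariance across genes, against 20 data sets simulated with no effect and the fitted means and spreads. These simulations draw genes independently, so their range is narrower than that of real data, and the shared pools could not be split because each part would hold 1 pool.

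The procedure was tested on simulated data with the same 6 pools. Of genes altered by folds of 1.5, 2 and 4, it called 20%, 56.1% and 72.7% in the THX against Long comparison, 27.7%, 64.2% and 86.2% in Long against Short, and 22.4%, 60.6% and 84.6% in THX against Short. It made 112, 133 and 122 calls, of which 14, 16 and 12 were of genes that had not been altered, and DESeq2 made 160, 185 and 157, of which 40, 46 and 31 were. The list of cytosolic ribosomal proteins, shifted by 0.3 on the log2 scale once per comparison, was recovered at medians of 0.298, 0.339 and 0.277, and camera with an estimated correlation called it (adjusted p = 0.0139, 0.0153 and 0.0156). Genes were drawn independently in these simulations too. The recovery therefore does not show that this test would call such a shift among correlated genes. Alternatives covered the scaling, the filter, the spread estimate, the tool, the thresholds, the pools used, a term for the pool number and the omission of each pool in turn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.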

Results

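The choroid plexus is the tissue whose epithelium secretes cerebrospinal fluid. It was collected from ewes in short days (Short), in long days (Long) and in long days after surgical removal of the thyroid gland (THX). RNA was extracted from each ewe and then mixed into 6 pools of 3 to 4 ewes, 2 pools per group. Reads per gene were counted after sequencing of polyA RNA. The pools held 82100653 and 48282883 counts in the Short group, 56083949 and 54384558 in the Long group, and 57551684 and 70185932 in the THX group. Of the 33609 genes listed, 18019 had enough counts to be tested. Transthyretin (TTR), the thyroid hormone carrier made by the choroid plexus epithelium, had the highest level, at 108422 ± 1144 (SD, n = 2) CPM in Long pools, where CPM are counts scaled to a common library total. All levels below are the mean CPM ± SD of the 2 pools of a group, and the p-values measure the spread between pools of ewes, not between ewes. On a principal component analysis of all tested genes the first component held 30.9% of the variance and the second 26.4%, and 3 pools lay at their ends. On the first component THX pool 2 lay at 42.7, where the next highest pool lay at 8.6, and Short pool 1 lay at −38.4, where the next lowest lay at −18.7. THX pool 1 lay at −47.8 on the second, where the next lowest lay at −5.25.

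The comparison of THX with Long pools asked what loss of the thyroid does to the choroid plexus at a constant day length. The decreases in THX pools included HR and KLF9, known targets of the thyroid hormone receptor that the naming rule gave in every comparison. HR, the hairless corepressor that binds this receptor, fell 7.70-fold, from 23.5 ± 0.203 to 3.06 ± 0.428 CPM (n = 2 per group; log2 difference −2.94, SE 0.128, adjusted p = 0.000835). KLF9, a transcription factor induced by thyroid hormone, fell from 91.6 ± 2.33 to 35.1 ± 1.41 CPM (log2 difference −1.38, SE 0.089, adjusted p = 0.0053). GALNT14, an enzyme that starts O-linked glycosylation, fell 13.3-fold, from 8.73 ± 0.434 to 0.655 ± 0.0949 CPM (log2 difference −3.74, adjusted p = 0.00385). NOXO1, an organiser subunit of a superoxide-producing oxidase, fell from 7.19 ± 0.209 to 1.27 ± 0.102 CPM (log2 difference −2.50, adjusted p = 0.00626).

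Some transporter and signalling genes were among the other genes that fell in THX pools. The 61 solute and drug transporters did not pass as a set by camera (33 above and 28 below 0, median log2 difference 0.03, adjusted p = 0.922). SLC6A20, a proline transporter, fell from 131 ± 5.04 to 45.4 ± 9.83 CPM (log2 difference −1.53, adjusted p = 0.0179). SLC1A7, a glutamate transporter, fell by 1.62 on the log2 scale. KIT, the stem cell factor receptor that is also a mast cell marker, fell from 36.6 ± 1.30 to 12.9 ± 3.48 CPM. SERTAD4 (log2 difference −2.19), NPPC (−2.13), which encodes C-type natriuretic peptide, TKTL1 (−1.59) and the cadherin CDH23 (−1.54) fell as well. PFKP, a glycolytic phosphofructokinase, fell from 436 ± 47.5 to 165 ± 33.4 CPM. CHGA, the granin chromogranin A, fell from 6850 ± 148 to 3595 ± 37.9 CPM. Of the epithelial markers, the serotonin receptor HTR2C fell from 44.2 ± 0.159 to 26.7 ± 0.784 CPM (adjusted p = 0.0203) and CAB39L from 459 ± 10.3 to 296 ± 7.59 CPM (adjusted p = 0.0274).

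Fewer genes rose. SOST, a secreted antagonist of Wnt signalling, rose from 5.36 ± 0.165 to 16.9 ± 1.79 CPM (log2 difference 1.66, SE 0.146, adjusted p = 0.016). SOSTDC1, a related antagonist of Wnt and BMP signalling, rose from 2.43 ± 0.13 to 6.60 ± 0.231 CPM (log2 difference 1.44, SE 0.174, adjusted p = 0.0337). LINGO1 (identifier 101117451, 1 of the identifiers that share this symbol) rose from 9.73 ± 0.815 to 27.0 ± 0.26 CPM (log2 difference 1.47, adjusted p = 0.00799). Ceruloplasmin (CP), a copper-carrying ferroxidase, rose from 43.1 ± 6.06 to 82.8 ± 8.95 CPM, and the apolipoprotein APOA1 rose from 2225 ± 261 to 3977 ± 247 CPM (adjusted p = 0.0417 and 0.0361). CSAD, an enzyme of taurine synthesis, rose from 346 ± 1.84 to 511 ± 0.186 CPM. TPBGL, PYCR1 and DEGS2 made up the rest of the increases, with log2 differences of 1.34, 0.72 and 0.65.

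In all, 51 of 18019 genes changed, 9 upward and 42 downward, by the quasi-likelihood test of edgeR, and in each of the 51 both THX pools lay on the same side of both Long pools. Such separation of the 2 groups was seen in 37.2% of all tested genes, against 33.3% by chance. TTR (129789 ± 15440 CPM in THX pools, log2 difference 0.26, SE 0.095, adjusted p = 0.473) did not pass. The receptor THRB (14.5 ± 3.00 against 13.4 ± 0.0892 CPM, log2 difference 0.11, adjusted p = 0.959) and the deiodinase DIO1 (log2 difference −0.13, adjusted p = 0.987) did not pass either, and the deiodinase DIO3 had too few counts to be tested. The number of changed genes was 24 without Short pool 1, 24 without Short pool 2, 9 without Long pool 1, 2 without Long pool 2, 13 without THX pool 1 and 37 without THX pool 2. Of these, 21, 21, 5, 2, 10 and 21 were among the 51. HR passed without each of the 6 pools (highest adjusted p over all alternatives 0.0146), whereas KLF9, GALNT14 and NOXO1 missed the threshold without Long pool 2 (adjusted p = 0.0882, 0.0526 and 0.0956) at log2 differences of −1.41, −3.69 and −2.47. Of the 9 increases, SOSTDC1, TPBGL, CP, APOA1, PYCR1, DEGS2 and CSAD passed in none of the 6 fits that left out 1 pool (adjusted p from 0.0564 to 0.404), and SOST and LINGO1 passed in 3 and 4 of them. The log2 differences of the first 7 stayed positive over all alternatives, from 0.52 to 0.57 for CSAD, 0.67 to 0.73 for PYCR1, 0.72 to 0.96 for APOA1 and 0.81 to 1.09 for CP. Among the decreases, NPPC, HTR2C, CAB39L and LUM, a gene of the matrix list, passed in none of the 6 fits that left out 1 pool. Their log2 differences in these fits ran from −2.42 to −1.89, −0.76 to −0.70, −0.66 to −0.61 and −0.81 to −0.66. PFKP passed in 1 of these fits, SERTAD4, SLC1A7, TKTL1, CDH23 and KIT in 2, and CHGA and SLC6A20 in 4. DESeq2 called 440 genes, 180 up and 260 down, among them all 51, and edgeR run on only the 4 pools compared called 22.

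**Figure D1:**
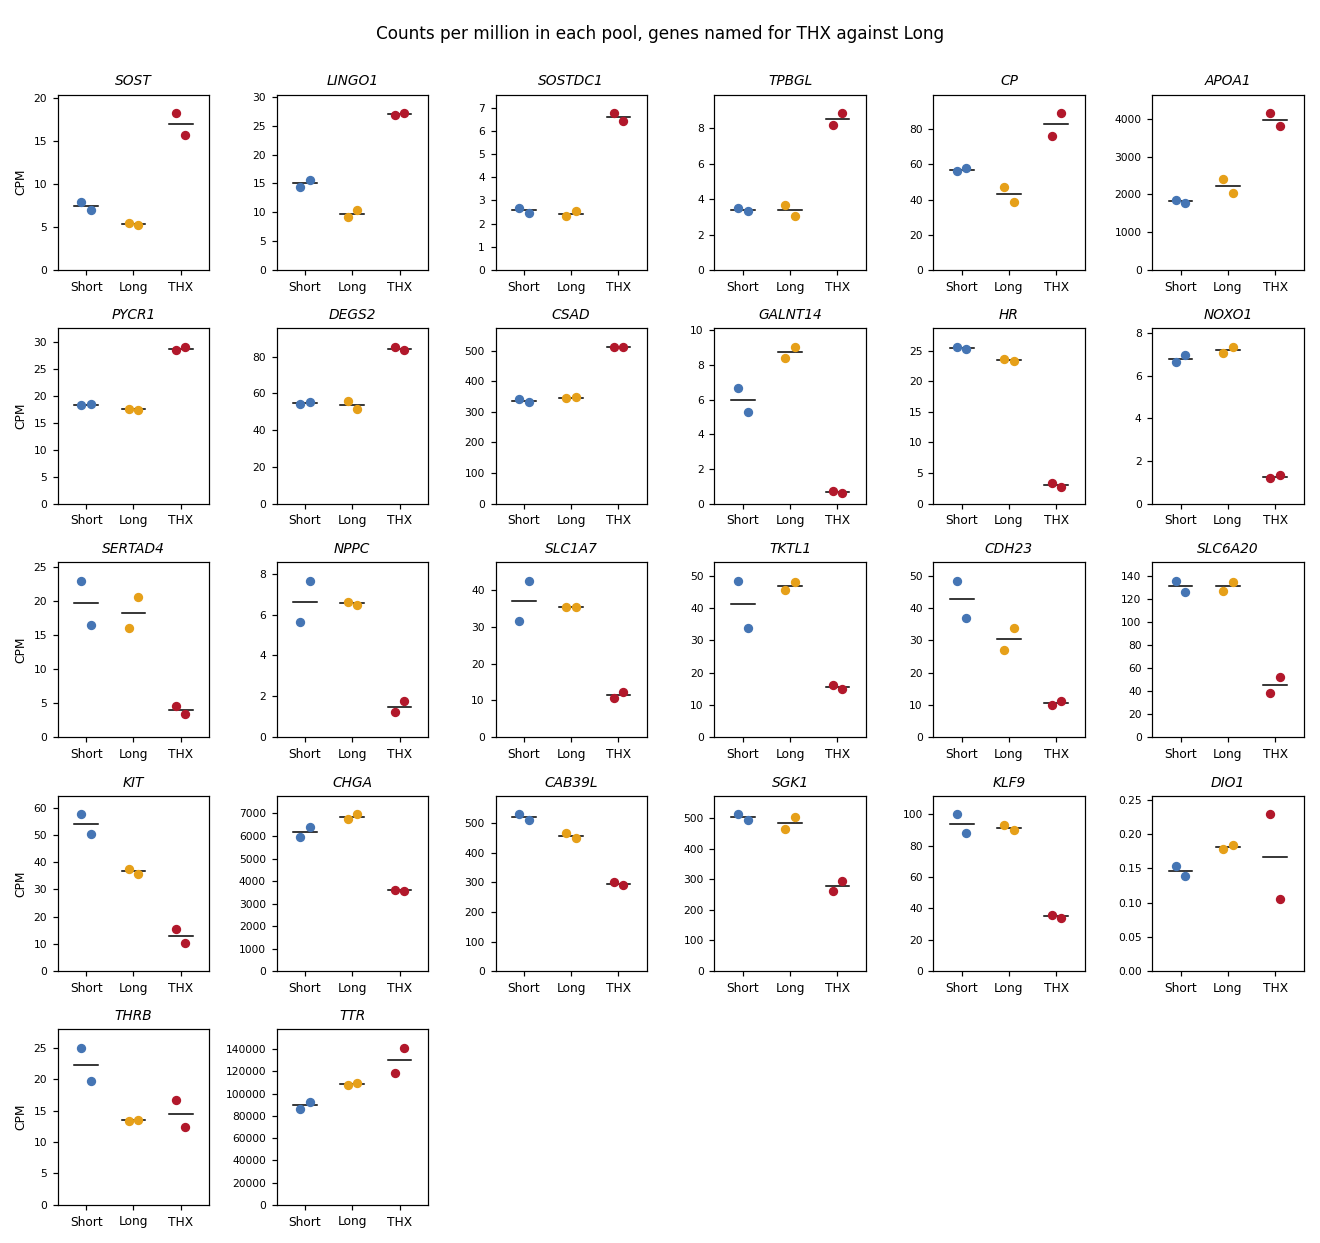
CPM (vertical axes from 0, with a scale of their own for each gene) of the genes named for THX against Long, with 1 point for each of the 6 pools, a bar at the mean of the 2 pools of a group, and colours for the Short, Long and THX groups. HR lay at a mean of 3.06 in THX pools against 23.5 in Long pools, whereas TTR had means of 89553, 108422 and 129789 in the Short, Long and THX groups.

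The list of 29 thyroid hormone responsive genes fell as a set in THX relative to Long pools (median log2 difference −0.09, adjusted p = 4.63e-07). The call was lost at an adjusted p = 0.379 with an estimated correlation. HR and KLF9 were the members that fell over all genes tested, and 1 rose and 4 fell when adjusted over the list alone. In log2 difference 18 of the 29 lay below 0, as did 18 in Long relative to Short pools (median −0.05, adjusted p = 0.317). The list was not tested without HR and KLF9. The 31 genes of fatty acid synthesis and oxidation also fell as a set (median −0.16, adjusted p = 8.28e-05, but 0.614 with an estimated correlation). None of them passed over all genes tested and 5 were lower adjusted over the list alone. ACACB, which makes the malonyl-CoA that restrains fat oxidation, and the fatty acid carrier FABP5 had log2 differences of −0.92 and −0.66 (adjusted p = 0.0717 and 0.123). The 22 genes of thyroid hormone transport, metabolism and receptors rose as a set (median 0.08, adjusted p = 0.0127, and 0.585 with an estimated correlation), with no member past the test and 2 higher adjusted over the list alone. RXRA, the amino acid and hormone transporter SLC7A5 and THRA had log2 differences of 0.35, 0.60 and 0.25. That call was lost without Long pool 1 (median 0.06, adjusted p = 0.117), without THX pool 1 (median −0.04, adjusted p = 0.59) and among genes with a mean CPM of at least 5 (adjusted p = 0.0607). The 25 glucocorticoid and steroid response genes passed in the downward direction (14 below and 11 above 0, median −0.02, adjusted p = 0.0026, and 0.614 with an estimated correlation), with KLF9 and SGK1 past the test. SGK1, an aldosterone- and glucocorticoid-induced kinase, fell from 484 ± 28.4 to 278 ± 23.0 CPM, and passed in 1 of the 6 fits that left out 1 pool. This call was lost without Long pool 1 (median 0.03, adjusted p = 0.0575) and without THX pool 2 (adjusted p = 0.474).

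Genes of the stroma were lower as sets in THX than in Long pools. The 63 collagen and matrix genes fell (median log2 difference −0.22, 46 of 63 below 0, adjusted p = 2.64e-05, and 0.379 with an estimated correlation). Lumican (LUM), a collagen-binding proteoglycan, was the member that fell over all genes tested, from 90.6 ± 6.57 to 54.4 ± 3.24 CPM, and 1 rose and 7 fell adjusted over the list alone. The collagens COL3A1 and COL11A1 and the elastic fibre protein FBLN5 had log2 differences of −0.78, −1.15 and −0.72 (adjusted p = 0.16, 0.193 and 0.174). Markers of fibroblasts and leptomeninges fell as a set of 25 (median −0.14, adjusted p = 0.000105, and 0.614 with an estimated correlation), with LUM past the test and 3 lower adjusted over the list alone. Without THX pool 1 the median was −0.05 and the adjusted p 0.0895. Markers of pericytes and smooth muscle also fell as a set (median −0.16, 17 of 20 below 0, adjusted p = 0.0127, and 0.725 with an estimated correlation). That call was lost without Long pool 1 (median −0.14) or THX pool 1 (median −0.15). The 24 endothelial markers did not pass (median −0.03, adjusted p = 0.0933). THX pool 1, which lay apart on the second component, had the lowest fibroblast level of the 6 pools, at −0.29 on a log2 scale centred on the pools' mean. The level was −0.08 in THX pool 2, 0.11 and 0.05 in the Long pools and −0.04 and 0.27 in the Short pools.

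Across this comparison, 16 of the 39 lists tested passed, 5 upward and 11 downward. Some genes, KLF9 and LUM among them, belong to more than 1 list, so the list calls are not independent of each other. The 17 oligodendrocyte markers fell (median −0.27, adjusted p = 0.00211, and 0.379 with an estimated correlation), with 1 member lower adjusted over the list alone. Among genes with a mean CPM of at least 5 that call was lost (median −0.10, adjusted p = 0.0607). The 11 granulocyte and mast cell markers fell (median −0.16, adjusted p = 0.00211, and 0.379 with an estimated correlation), with KIT past the test and the mast cell receptor subunit MS4A2 at −2.64 (adjusted p = 0.222). That call was lost without Long pool 1 (adjusted p = 0.104) or THX pool 1 (0.0818). The 32 immediate early genes, which respond within minutes to stimulation, fell as a set (median −0.25, 27 below 0, adjusted p = 1.47e-05, and 0.725 with an estimated correlation). FOSB and CCN1 were at −1.04 and −0.72 without passing (adjusted p = 0.468 and 0.322). That set call was lost without THX pool 1 (median −0.17, adjusted p = 0.084). The 74 cytosolic ribosomal protein genes rose (median 0.14, 71 above 0, adjusted p = 1.11e-05, and 0.766 with an estimated correlation), a call lost without THX pool 2, the pool apart on the first component (median 0.01, adjusted p = 0.997). Motile cilia genes (39 of 49 above 0, median 0.10, adjusted p = 0.00743), ependymal markers (13 of 18 above 0, median 0.10, adjusted p = 0.00926) and interferon response genes (27 of 34 above 0, median 0.18, adjusted p = 0.0093) rose as sets. Their adjusted p was 0.725, 0.614 and 0.766 with an estimated correlation. The cilia and ependymal calls were lost without THX pool 2 (medians 0.04 and 0.11, adjusted p = 0.464 and 0.425) and the interferon call without THX pool 1 (median −0.05, adjusted p = 0.865). The cilia and interferon calls were also lost without Long pool 1 (medians 0.09 and 0.09, adjusted p = 0.0575 and 0.197).

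Lymphocyte markers (21 of 24 below 0, median −0.34, adjusted p = 0.0134) and antigen presentation genes (12 of 15 below 0, median −0.16, adjusted p = 0.0204) were the other sets that fell in THX pools. Their adjusted p was 0.766 and 0.725 with an estimated correlation. The lymphocyte call was lost without Long pool 2 (median −0.32) or THX pool 1 (median −0.19). It was also lost among genes with a mean CPM of at least 5 (median −0.27, adjusted p = 0.227). The antigen presentation call was lost without Long pool 1, Long pool 2, THX pool 1 or THX pool 2, with medians of −0.20, −0.11, −0.18 and −0.23. The 29 choroid plexus epithelium markers did not pass (adjusted p = 0.647), and their median of 0.05 was opposite in sign to the downward direction of the test. HTR2C and CAB39L fell in that list, and 3 were higher and 6 lower adjusted over the list alone. The 38 genes of ion transport and fluid secretion did not pass either (median −0.08, adjusted p = 0.94), with 4 higher and 1 lower adjusted over the list alone. WNK4, a kinase that regulates chloride cotransport, the sodium pump subunit ATP1B2 and the kinase STK39 had log2 differences of 0.68, 0.41 and 0.57 (adjusted p = 0.101, 0.11 and 0.122). The circadian clock list did not pass (adjusted p = 0.647).

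**Figure D2:**
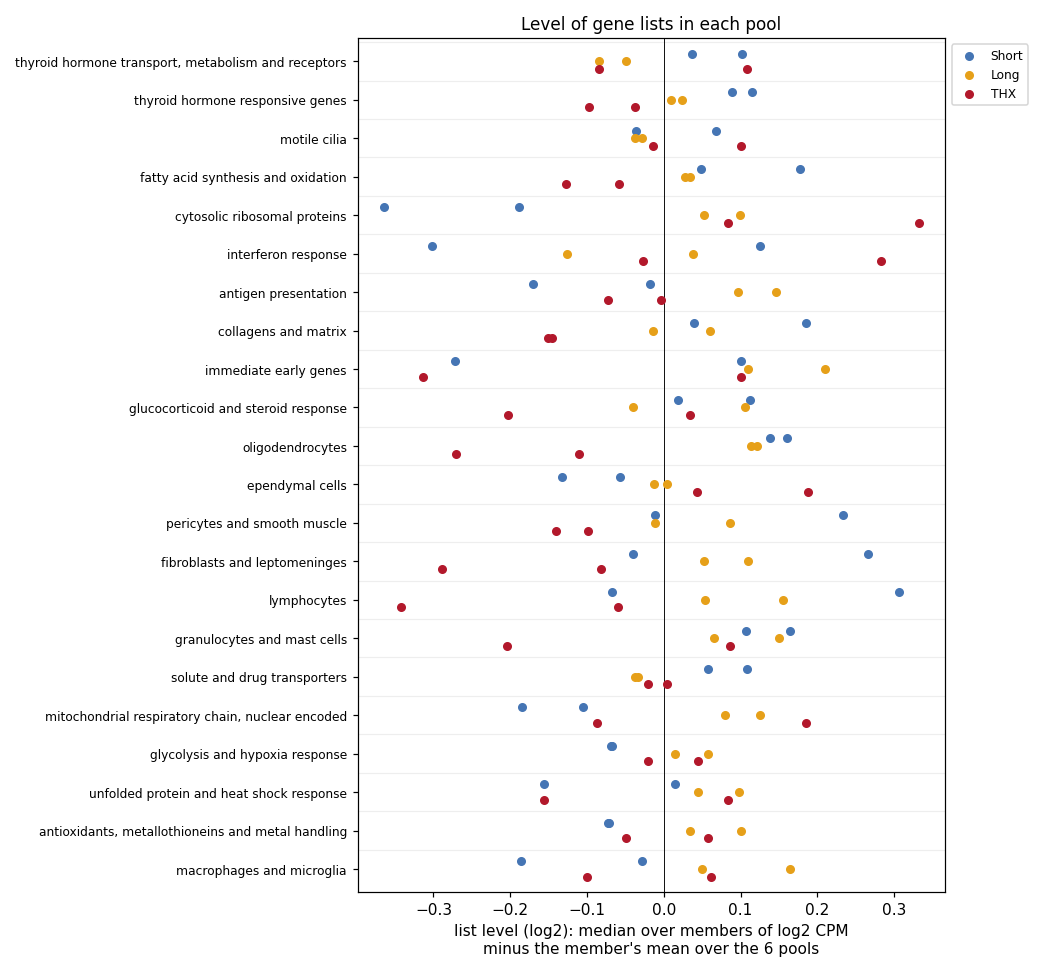
Level of each plotted gene list in each of the 6 pools, on a log2 scale, as the median over the list's members of log2 CPM minus the member's mean over the pools, with 1 point per pool coloured by group. Ribosomal protein genes lay at −0.36 and −0.19 in the Short pools and between 0.05 and 0.33 in the 4 long-day pools.

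The comparison of Long with Short pools asked what day length does in ewes with an intact thyroid. No single gene passed the test over all genes. HR was at 23.5 ± 0.203 CPM in Long and 25.4 ± 0.194 CPM in Short pools (log2 difference −0.11, SE 0.114, adjusted p = 0.663). KLF9 was at 91.6 ± 2.33 and 94.1 ± 8.27 CPM (log2 difference −0.04, SE 0.087, adjusted p = 0.852). THRB, a thyroid hormone receptor, was at 13.4 ± 0.0892 CPM in Long and 22.3 ± 3.74 CPM in Short pools (log2 difference −0.73, adjusted p = 0.342), without passing. HTR2C was at 44.2 ± 0.159 and 69.9 ± 0.711 CPM (log2 difference −0.66, adjusted p = 0.342), which did not pass either. TTR was at 108422 ± 1144 and 89553 ± 4463 CPM (log2 difference 0.28, SE 0.095, adjusted p = 0.342), and DIO1 had a log2 difference of 0.29 (adjusted p = 0.833). The natriuretic peptide receptor NPR3 was at 9.85 ± 0.758 and 19.7 ± 1.62 CPM. The bicarbonate transporter SLC4A10, the clock repressor NFIL3, the clock gene PER2 and VMO1, a secreted protein in the list of seasonal timing, had log2 differences of −0.73, 0.47, −0.56 and 0.58. The adjusted p of each of these 5 genes was 0.342.

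The count of 0 changed genes came from edgeR, in which 2486 of 18019 genes had an unadjusted p below 0.05, and limma-voom also called 0. In THX against Long pools 1636 genes had an unadjusted p below 0.05 by edgeR, so the numbers of calls do not show which change was broader. DESeq2 called 156, of which 52 were higher and 104 lower in Long pools, among them THRB, HTR2C and NPR3. Over all alternatives the adjusted p ran from 0.0262 to 0.871 for THRB, 6.31e-08 to 0.871 for HTR2C and 1.4e-07 to 0.871 for NPR3. The groups were separated in 53.5% of genes, against 33.3% by chance. In simulated data of the same size, 64.2% of genes altered by a fold of 2 and 27.7% of those altered by a fold of 1.5 were called. The count was 1 without Short pool 2 and 4 without Long pool 1.

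Sets of genes did differ between day lengths under the preset correlation. Cytosolic ribosomal protein genes rose in Long relative to Short pools (median log2 difference 0.35, 73 of 74 above 0, adjusted p = 9.33e-38, and 0.635 with an estimated correlation). Of these, 68 were higher adjusted over the list alone. RPL11 was at 591 ± 7.60 against 452 ± 34.6 CPM, and both Long pools lay above both Short pools in the list's level. Nuclear genes of the mitochondrial respiratory chain rose as a set (median 0.27, 54 of 57 above 0, adjusted p = 6.72e-18, and 0.635 with an estimated correlation), with NDUFA8, a subunit of complex I, at a log2 difference of 0.39. Solute and drug transporters fell as a set (median −0.15, 46 of 61 below 0, adjusted p = 0.00527, and 0.635 with an estimated correlation), with the monocarboxylate transporter family member SLC16A12 and the vitamin C transporter SLC23A2 at −0.44 and −0.41. These 3 calls remained without each of the 6 pools.

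Immediate early genes rose as a set in Long pools (28 of 32 above 0, median 0.24, adjusted p = 0.000245, and 0.747 with an estimated correlation), with FOS at a log2 difference of 1.34 (adjusted p = 0.349). That call was lost without Short pool 1, at the low end of the first component (adjusted p = 0.186). Genes of the unfolded protein and heat shock response rose as a set (32 of 41 above 0, median 0.15, adjusted p = 0.000245, and 0.688 with an estimated correlation), with 1 member higher adjusted over the list alone. The chaperones HSPB1 and HSPA1A had log2 differences of 0.51 and 0.84, and the call was lost without Short pool 2 (adjusted p = 0.13). Markers of macrophages and microglia (22 of 27 above 0, median 0.21, adjusted p = 0.00538) and antigen presentation genes (12 of 15 above 0, 3 higher adjusted over the list alone, adjusted p = 0.00579) rose as sets, each with an adjusted p of 0.635 with an estimated correlation. The macrophage call was lost without Short pool 1 (0.121) or Long pool 2 (0.162) and the antigen presentation call without Short pool 1 (0.186). Antioxidant and metal handling genes rose as a set (27 of 43 above 0, median 0.13, adjusted p = 0.0192, and 0.726 with an estimated correlation). Glycolysis and hypoxia genes rose as a set (26 of 34 above 0, median 0.11, adjusted p = 0.048, and 0.635 with an estimated correlation). Collagen and matrix genes fell as a set (44 of 63 below 0, median −0.07, adjusted p = 0.0177, and 0.635 with an estimated correlation). These 3 calls were lost without Short pool 2, at medians of 0.13, 0.11 and −0.03. They were also lost without Long pool 2, at medians of 0.10, 0.08 and −0.09. The glycolysis call was also lost under scaling by total counts (adjusted p = 0.0718). Of 39 lists tested, 10 passed, 8 upward and 2 downward. Without Short pool 1 there were 14, 5 upward and 9 downward, of which 7 were among the 10, and without Long pool 2 there were 6.

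The comparison of THX with Short pools set the same thyroidectomised pools against the other intact group, so that thyroid state and day length differed together. Among named genes with a mean CPM of at least 2, GALNT14, HR and NOXO1 again had the largest decreases (log2 differences −3.19, −3.06 and −2.42, adjusted p = 0.00553, 0.0011 and 0.00553). KLF9 fell from 94.1 ± 8.27 to 35.1 ± 1.41 CPM (log2 difference −1.43, SE 0.089, adjusted p = 0.00437). HTR2C fell from 69.9 ± 0.711 to 26.7 ± 0.784 CPM (log2 difference −1.39, SE 0.073, adjusted p = 0.00168). KIT, the neural gene CTNND2 and the cadherin CDH23 fell by 2.06, 1.75 and 2.03 on the log2 scale. The calls of KIT and CTNND2 were lost without Short pool 1, at log2 differences of −1.96 and −1.60. Cystatin C (CST3), a secreted protease inhibitor, rose from 2212 ± 55.5 to 3514 ± 163 CPM (adjusted p = 0.0241). The growth factor carrier IGFBP2 rose from 1290 ± 62.4 to 2605 ± 402 CPM (adjusted p = 0.0237). COMP, a cartilage matrix protein, VMO1, SOSTDC1, SOST and APOA1 rose as well, with log2 differences of 1.52, 1.41, 1.35, 1.18 and 1.13 (adjusted p = 0.036, 0.038, 0.0306, 0.0267 and 0.0145). In the 6 fits that left out 1 pool, COMP and SOSTDC1 passed only without THX pool 1, CST3, IGFBP2 and SOST in 2 fits, VMO1 in 3 and APOA1 in 4. TTR was at 129789 ± 15440 CPM against 89553 ± 4463 CPM (log2 difference 0.54, SE 0.095, adjusted p = 0.058). It did not pass, but passed under 6 of 17 alternatives (adjusted p from 3.75e-05 to 0.249).

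A total of 165 genes changed by edgeR, 57 upward and 108 downward, and both groups were separated in each of them. Such separation was seen in 52.5% of all tested genes, against 33.3% by chance. Of the epithelial markers, IGFBP2 rose, and HTR2C, CAB39L and klotho (KL), a coreceptor for fibroblast growth factors, fell, KL from 1188 ± 127 to 661 ± 75.4 CPM. The list as a whole did not pass (adjusted p = 0.11). WNK4 and ATP1B2 rose in the list of ion transport and fluid secretion (log2 differences 0.97 and 0.45, adjusted p = 0.0241 and 0.0454), which did not pass either (adjusted p = 0.122). NPR3, the endothelin receptor EDNRB and the clock gene NR1D2 fell by 1.17, 0.48 and 0.46 on the log2 scale. The count was 10 without Short pool 1, 36 without Short pool 2, 16 without Long pool 1, 16 without Long pool 2, 1087 without THX pool 1 and 80 without THX pool 2. HR, KLF9, GALNT14 and HTR2C passed without each pool, WNK4 and CAB39L in 3 of these 6 fits, and KL, ATP1B2, NPR3, EDNRB and NR1D2 only without THX pool 1. The share of decreases varied as well, with 596 genes up and 491 down without THX pool 1, 849 up and 879 down by DESeq2, and 49 up and 210 down under scaling by total counts.

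**Figure D3:**
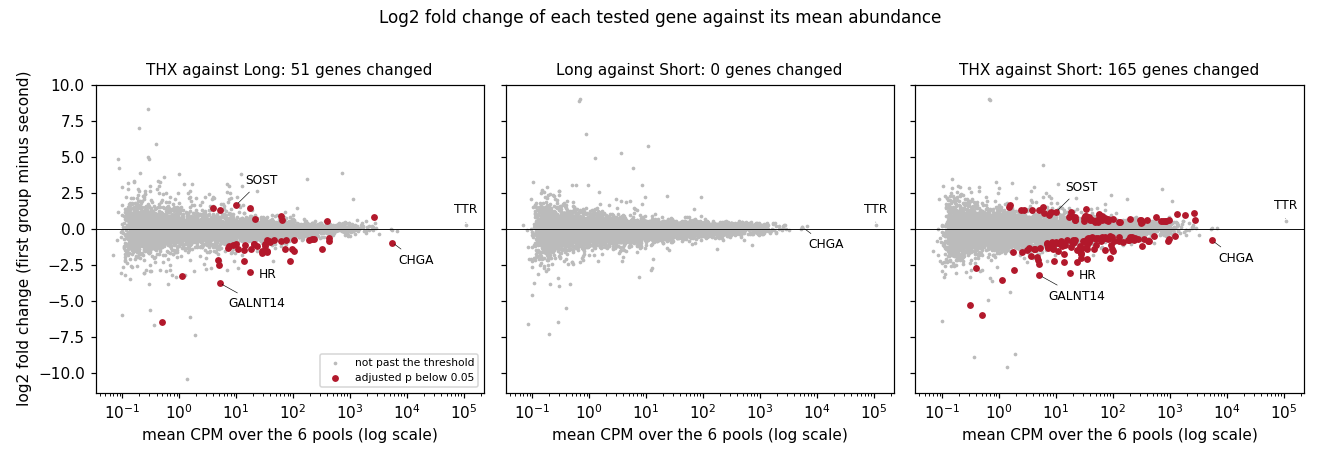
Log2 fold change of each of the 18019 tested genes (vertical axis) against its mean CPM over the 6 pools (log axis), with 1 panel per comparison and red points for genes with an adjusted p under the threshold of 0.05. There are 51 red points for THX against Long, 0 for Long against Short and 165 for THX against Short, and the point of TTR lies farthest to the right.

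Collagen and matrix genes fell as a set in THX relative to Short pools (51 of 63 below 0, median log2 difference −0.29, adjusted p = 3.31e-07, and 0.48 with an estimated correlation). The metalloproteinase inhibitor TIMP3, the collagen crosslinking enzyme LOX, LUM and SPARC were the members that fell over all genes tested (log2 differences −1.13, −1.04, −0.60 and −0.47), and 13 were lower adjusted over the list alone. LOX, LUM and SPARC passed only without THX pool 1 when 1 pool was left out, and TIMP3 in 2 of the 6 fits. Thyroid hormone responsive genes fell as a set of 29 (median −0.31, adjusted p = 2.29e-06, and 0.48 with an estimated correlation), with HR and KLF9 lower over all genes tested and 3 lower adjusted over the list alone. Fatty acid genes fell as a set of 31 (median −0.18, adjusted p = 0.000413, and 0.662 with an estimated correlation), with 8 lower adjusted over the list alone. All 74 ribosomal protein genes lay above 0 (median 0.48, adjusted p = 5.19e-41, and 0.662 with an estimated correlation), and 69 were higher adjusted over the list alone. These 4 set calls remained without each of the 6 pools. Respiratory chain genes rose as a set (52 of 57 above 0, median 0.21, adjusted p = 2.29e-06, and 0.802 with an estimated correlation), a call lost without THX pool 2 (adjusted p = 0.0873). Pericyte and smooth muscle markers fell as a set (17 of 20 below 0, median −0.26, adjusted p = 0.00475, and 0.663 with an estimated correlation) except without Short pool 2 (0.355). Fibroblast markers fell as a set (18 of 25 below 0, median −0.34, adjusted p = 0.00322, and 0.663 with an estimated correlation) except without Short pool 2 (0.157) or THX pool 1 (0.127).

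Of the 39 lists tested in THX against Short pools, 12 passed, 5 upward and 7 downward. Complement and inflammatory genes rose as a set of 41 (26 above 0, median 0.12, adjusted p = 0.0479, and 0.802 with an estimated correlation). SERPING1 and CFB, a complement inhibitor and a complement protease, passed the test at 0.61 and 0.58, and 5 were higher adjusted over the list alone. That call was lost without Short pool 1 (median −0.01, adjusted p = 0.502), THX pool 1 (0.0517) or THX pool 2 (0.107). Solute and drug transporters fell as a set of 61 (median −0.13, adjusted p = 0.0439, and 0.662 with an estimated correlation), with SLC6A20, SLC6A15 and SLC16A9 past the test at −1.53, −0.97 and −0.76. That call was lost without Short pool 1 (0.0883), Short pool 2 (0.058) or THX pool 2 (0.0813). When 1 pool was left out, SERPING1, CFB, SLC6A15 and SLC16A9 passed only without THX pool 1, and SLC6A20 passed in 3 of the 6 fits. Ependymal markers rose (median 0.22, adjusted p = 0.0101), oligodendrocyte markers fell (median −0.36, adjusted p = 0.0308) and interferon response genes rose (median 0.18, adjusted p = 0.0308), with adjusted p = 0.662, 0.662 and 0.802 with an estimated correlation. The ependymal call was lost without THX pool 2 (median 0.14). The oligodendrocyte call was lost without Short pool 2 (median −0.42) or THX pool 1 (median −0.30). The interferon call was lost without Short pool 1 (median 0.04) or THX pool 1 (median 0.02). The oligodendrocyte and interferon calls were also lost among genes with a mean CPM of at least 5 (adjusted p = 0.138 and 0.0622).

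Genes that changed in THX pools relative to Long pools were mostly also called relative to Short pools. Of the 9 that rose, 8 rose against both groups, and of the 42 that fell, 41 fell against both, where 0.028 and 0.252 would be shared if the calls were independent. Both comparisons use the same THX pools, so part of the excess may come from these shared pools. In 20 data sets simulated without any effect 0.3 genes on average were called against both, of 2.05 and 2 called on average in each comparison, too few calls to bound an overlap of the size observed. The thyroid hormone transport, immediate early, antigen presentation, motile cilia, lymphocyte, glucocorticoid and granulocyte lists passed against Long but not against Short pools. Their adjusted p by camera against Short pools ran from 0.0616 to 0.827, and the direction of antigen presentation genes was upward there. Immediate early and antigen presentation genes had also passed as higher in Long than in Short pools. The log2 differences of THX minus Long and of THX minus Short correlated across genes at r = 0.604, against 0.493 on average (0.46 to 0.518) in sets simulated without effect. Without THX pool 1 that value was 0.732, inside its simulated range of 0.663 to 0.733. Across all genes, which are not independent replicates, the log2 differences of THX minus Long and of Short minus Long correlated at r = 0.356, against 0.513 on average (0.485 to 0.542) in the simulated sets that share the Long pools in the same way. The covariance was 0.0669, against 0.0611 on average (0.0579 to 0.0657) in the simulated sets. The correlation with Short minus Long thus lay below every simulated set and the covariance above every one. Without THX pool 2 that correlation lay above the simulated average by 0.0357. Changes in only 1 of the 2 contrasts lower the correlation too, and the simulated sets held none. Its low value therefore does not argue against a shared change. The covariance minus its simulated average was −0.0083 without THX pool 1 and −0.0057 among genes with a mean CPM of at least 5. Because the covariance changed side, no direction could be given for a shared change of thyroidectomy and short days.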

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

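No called named gene took the opposite direction under any alternative, and no called list passed in the opposite direction. The direction of lists that missed the threshold was not checked, and the medians of some lists near 0 crossed it. The number of genes changed in THX against Long pools was 51, and stayed within 1.5 times that under total counts (50), DESeq2's size factors in edgeR (51), a mean CPM of at least 5 (48), the 10 most abundant genes left out (48), robust spread (61) and limma-voom (45). It was 204 with no filter, 440 by DESeq2, 22 with only the 4 pools compared, 32 with a log2 difference of at least 1 added, 7 at an adjusted p under 0.01, and 2 to 37 when 1 pool was left out. The number of lists was 0 with an estimated correlation, 0 by fry, and 9 to 17 when 1 pool was left out.

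In Long against Short pools the number of genes was 156 by DESeq2 and 0 to 4 when 1 pool was left out, and 0 under the other alternatives. The number of lists was 0 with an estimated correlation, 0 by fry and 6 to 14 when 1 pool was left out. In THX against Short pools the 165 genes became 259 under total counts, 908 with no filter, 250 with robust spread, 1728 by DESeq2, 11 with only the 4 pools compared, 69 with a log2 difference of at least 1 added, 8 at an adjusted p under 0.01, and 10 to 1087 when 1 pool was left out. The number of lists was 0 with an estimated correlation, 0 by fry and 8 to 17 when 1 pool was left out. Scaling by total counts gave this comparison a median log2 difference of −0.11 over all genes.

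Whether pool numbers pair pools across groups is not stated. The differences between pool 1 and pool 2 correlated across genes at −0.059 between Short and Long, 0.211 between Short and THX and 0.067 between Long and THX. With a block for pool number, 48 genes changed in THX against Long, of which 41 were among the 51, 0 in Long against Short and 392 in THX against Short.

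The correlation of thyroidectomy with short days, minus its simulated value, was −0.157. It was −0.32 at a mean CPM of at least 5, −0.303 as Spearman's rho, and −0.211 to 0.0357 when 1 pool was left out. The covariance minus its simulated value was 0.0058, against −0.0057 at a mean CPM of at least 5 and −0.0083 to 0.0817 when 1 pool was left out, with the lowest without THX pool 1. Stricter thresholds give fewer calls by construction. For the other shifts, which went in either direction when a pool was left out, the cause was not tested. Where the pool belonged to neither group compared, the log2 differences hardly moved. For APOA1 in THX minus Long the difference was 0.838 with all pools and without either Short pool. Calls lost in such fits come with fewer pools to estimate the spread, not with a changed difference. A group left with 1 pool was assumed to vary like the other groups. Depth ran from 48282883 to 82100653 counts per pool, at which genes with few counts, such as DIO3, could not be tested.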

Other observations

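Several further genes fell in THX relative to Long pools. The genes named in these first sentences, down to NXNL1, were chosen after their values were seen. MLXIPL, the carbohydrate-responsive transcription factor that drives fat synthesis genes, fell by 1.40 on the log2 scale (SE 0.101, adjusted p = 0.00759), and OXCT1, the enzyme that lets cells use ketone bodies, fell by 0.67 (SE 0.08, adjusted p = 0.0336). The water channel AQP5 fell by 1.01 (SE 0.111, adjusted p = 0.0269), the potassium channel KCNK3 by 1.14 (SE 0.142, adjusted p = 0.0383) and the transcription factor NFIX by 0.76 (SE 0.073, adjusted p = 0.0191). A pair of genes best known from cone photoreceptors fell at low counts. ARR3, the cone arrestin, had 8 and 11 counts in the THX pools against 61 and 102 in the Long pools and 135 and 97 in the Short pools (adjusted p = 0.0361). NXNL1, which encodes a cone survival factor, had 0 and 1 counts in the THX pools against 44 and 52 in the Long pools, a ratio of 111 with a 95% counting interval from 19.5 to 4430 (adjusted p = 0.0269).

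The tests that weigh explanations of the 3 patterns below were chosen only after the result was seen, although the fits without 1 pool, with no filter and by DESeq2 that they draw on were planned.

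Ribosomal protein genes were higher in Long than in Short pools, with a median log2 difference of 0.35. The tables argue against 1 Short library as the whole source, since the median was 0.256 and 0.446 without either Short pool. Day length is a candidate explanation, since the THX pools, also from long days, had a median of 0.475 above Short pools and all 4 long-day pools lay above both Short pools, although thyroid state differs in that comparison too. Chance differences between pools stay open and cannot be told apart from day length, because the list level differed by up to 0.249 between the 2 THX pools, against 0.352 between the Long and Short means, with 2 pools per group.

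Matrix and fibroblast genes were lower in THX than in Long pools. The tables argue against 1 library as the whole source for the matrix genes, since the median of that list ran from −0.253 to −0.151 when 1 of the 4 pools was left out. The 95% interval of resampled members at the highest median was −0.297 to −0.072. Such intervals treat the members of a list as independent and do not measure the spread between pools. A lower share of all stromal and vascular cells and a change within fibroblasts cannot be told apart, since the endothelial median exceeded the fibroblast median by 0.112 with a 95% interval of resampled members from −0.083 to 0.398. For the fibroblast genes 1 library stays open as well, because their median ran from −0.401 to −0.048 when 1 of the 4 pools was left out, and was highest without THX pool 1. An effect of thyroidectomy on the stroma itself remains untested.

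Prolactin (PRL), a pituitary hormone, varied between pools of 1 group, at 581 CPM in THX pool 1 and 191 in THX pool 2 against 19.3 and 50.1 in the Long pools and 137 and 52.7 in the Short pools. CPM in this paragraph use total counts without TMM factors. All 9 other genes of a pituitary marker list of 10 were higher in THX pool 1 than in THX pool 2, with GH at 41.8 against 4.79 CPM and POMC at 30.3 against 8.29 CPM, so pituitary tissue or its RNA in some pools is a candidate source. The 10 genes, of which 4 also stand in a fixed list and whose level in the tissue itself is not known here, did not move together across all pools, since Long pool 2 had 44.1, 21.8 and 15.9 CPM of CGA, LHB and TSHB, against 34.3, 21.0 and 16.2 in THX pool 1, but 2.15 of GH and 2.46 of POMC. PRL did not pass against Long pools (log2 difference 3.51, adjusted p = 0.174) or Short pools (adjusted p = 0.148), although with no filter it passed against both (0.00865 and 0.0398) and by DESeq2 against Long (0.012), with ranges over the alternatives of 0.00865 to 0.718 and 0.0398 to 0.31. An effect of thyroidectomy on PRL cannot be told apart from tissue carried over, with 2 pools that differ from each other.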
